A study of Rattus norvegicus with 53 samples.

How the data were processed

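The data were 1-colour (Cy3) Agilent rat arrays of testis RNA, 53 in number, from 9 groups given in the labels. The deposited array files hold spot intensity values made with Agilent Feature Extraction 11.5.1.1, per the file headers, which include background subtraction in the processed signal. The deposited value table holds log2 values of the same arrays in which each row has a median of 0; column medians ran from -0.0584 to 0.0516, and after centring each gene these values correlated with the values used here at 0.9989. Its normalization between arrays is not given in the sources used here, so it served only as an alternative.

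From the array files, control spots and spots marked as non-uniform or as outliers of their probe were left out (0.53% to 1.05% of spots per array were so marked). Processed signals were scaled to a common 75th percentile of 1373, set to at least 2 (1.49% of spot values were at this floor), and taken as log2. Levels are given relative to that percentile. Spots of 1 probe were averaged. Of 30367 probes, 18758 were matched to 15715 gene symbols by accession, without versions, in a RefSeq table of the GRCr8 assembly, and list members under older symbols were resolved through synonyms that point to 1 gene. No genome was used. A probe was tested if it was well above background on at least 5 arrays (25217 probes). For a gene with several probes the one with the highest mean stood for it, which left 22171 genes, 13404 of them with a symbol. Named genes were checked for the direction of their other probes.

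Means of the 9 groups were fitted over all arrays with limma 3.58.1 (lmFit and eBayes, 2-sided) in R 4.3.3, with Benjamini-Hochberg adjustment within each comparison and an adjusted p under 0.05 as the threshold. Contrasts were each exposure against corn oil, both doses of a compound averaged, all 8 exposures averaged, an F test over the groups, 300 against 30 mg/kg/day, and each pair of compounds at a matched dose. The 30 gene lists, with 759 members of which 647 were measured, covered testis cell types, other cell types, hormone and lipid pathways, stress and immune responses and basic cell machinery. They were fixed before the data were examined, as were the groups, the tests of genes and lists, the alternatives other than leaving out slide 7, and the rule for named genes as first written. What was chosen later is given as such where it appears. Lists were tested with camera at a preset correlation of 0.01, adjusted over all lists and comparisons of a family. Camera with an estimated correlation and fry stand beside it. The standard error of a list's mean shift is that between arrays.

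Named genes were those passing the test, then, where fewer than 5 passed in a direction, the genes with the largest log2 fold change at an unadjusted p under 0.01 and, in addition to the rule as first written, well above background on at least 1 array of each group. Also named were 8 steroidogenic genes and up to 3 members of each called list. Some genes that the rule names are not reported here. Correlations between exposures were set beside simulated unchanged groups and beside values with the corn oil arrays divided into sets of 3.

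Alternatives were a normexp background correction with an offset of 50 (on median rather than mean spot signals, which the files do not carry), quantile normalization, median centring, other filters on dim probes, every probe on its own, slide as a fixed or random block, scan day or replicate number as a block, only the groups compared, array weights, eBayes with trend and robust options, the deposited value table, and leaving out each array in turn. The number of arrays sets the precision. The statistical steps were tested on simulated data before use. Figures were drawn with matplotlib 3.10.9.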

Results

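The series measured gene expression in the adult rat testis after exposure to plasticizers through the mother. Sprague-Dawley dams received corn oil alone or a plasticizer in corn oil by gavage, at a dose of 30 mg/kg/day or of 300 mg/kg/day, from gestational day 8 to postnatal day 21. Testis RNA of the offspring was taken at day 90. The plasticizers were DEHP (di(2-ethylhexyl) phthalate, a long-used phthalate diester), DINCH (diisononyl cyclohexane-1,2-dicarboxylate, which has a cyclohexane ring in place of the aromatic ring of a phthalate), BDB (1,4-butanediol dibenzoate, a diester of benzoic acid) and DOS (dioctyl succinate, a diester with no ring). The comparisons ask how each compound and dose differs from corn oil, and how the newer compounds compare with DEHP at matched doses. Each of the 9 groups held 6 animals from separate litters, except DINCH at 30 mg/kg/day with 5 (replicate 2 of that group was not analysed here). Groups are named below by compound and dose. All 53 arrays were of 1 colour. Between 43821 and 48797 of their spots were well above background, 0 were saturated, and pairs of arrays correlated across probes at 0.9855 to 0.9943. The number of arrays limits the precision. For a gene of median spread, the 95% interval of a comparison of 6 arrays with 6 reached 0.21 to either side on the log2 scale, or 1.15-fold. This interval is not adjusted for the number of genes tested, so larger changes can also fail to pass.

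Slide was a larger source of variation than exposure. The arrays lay on 8 slides scanned on 3 days, and limma found 4209 of 22029 genes to differ between slides at an adjusted p under 0.05. The first principal component held 9.66% of the variance, and slide accounted for 91.9% of its spread against 5.25% for group. Slides 4 and 8 carried 0 corn oil arrays and the other slides 1 each, so within-slide values rest on single corn oil arrays.

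No gene passed the test in any of the 8 comparisons with corn oil. Among 22171 genes tested with limma, 0 passed an adjusted p of 0.05 for each compound and dose. At an unadjusted p under 0.05 there were 1363 genes in DEHP 30, 742 in DEHP 300, 745 in DINCH 30, 584 in DINCH 300, 627 in BDB 30, 656 in BDB 300, 945 in DOS 30 and 2505 in DOS 300, where chance alone gives 1109. These counts moved with the processing, for DEHP 30 to 816 with only the groups compared and for DINCH 30 to 1499 with a normexp background correction. With both doses of a compound averaged limma also called 0 genes, with 1115, 683, 733 and 1250 at an unadjusted p under 0.05 for DEHP, DINCH, BDB and DOS. An F test in limma over all 9 groups gave 0 genes (smallest adjusted p = 0.999), with 1016 at an unadjusted p under 0.05. Data were simulated over 22029 genes from the shuffled deviations of all arrays from their group means. In DEHP 300, 200 genes per run were changed, by 1.5-, 2- and 4-fold together. The same test recovered 67.8% of genes changed 1.5-fold, 85.7% of those changed 2-fold and 97.3% of those changed 4-fold. Recovery with fewer changed genes was not simulated.

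**Figure D1:**
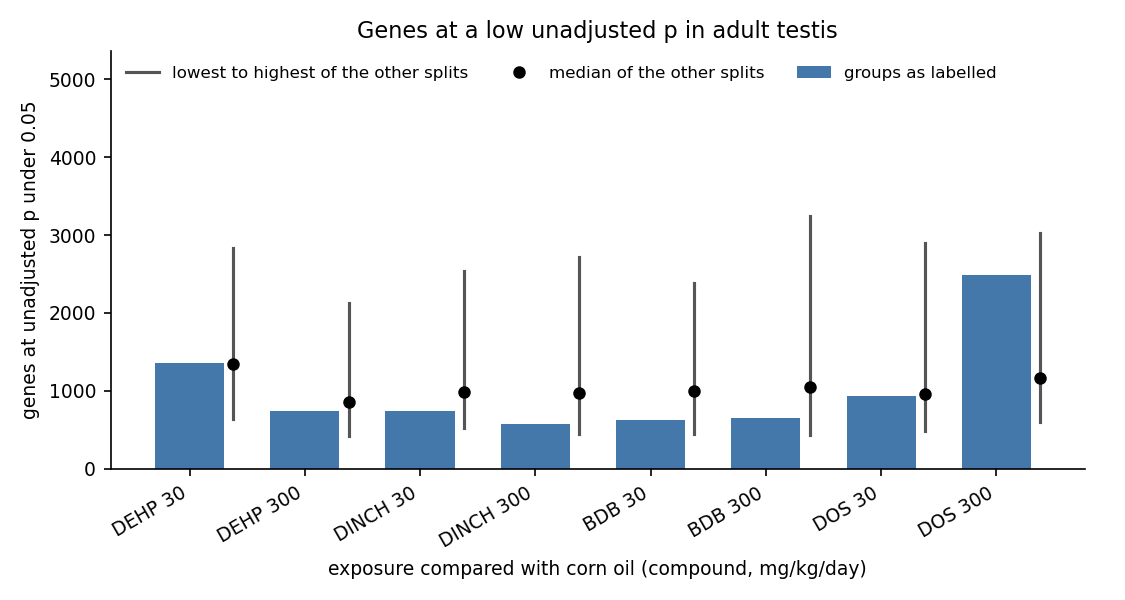
Bars give the number of genes at an unadjusted p under 0.05 (vertical axis) for each exposure against corn oil (horizontal axis), over the 22029 genes with a value on every array. Lines span the lowest to highest counts of other splits of the same arrays and dots mark their medians, with DOS 300 at 2491 genes and the highest of its other splits at 3023.

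Mogat3, an acyltransferase of triglyceride synthesis, was the 1 gene to pass when the 8 exposures were averaged and set against corn oil. It was higher by 1.53 on the log2 scale (SE 0.28, limma adjusted p = 0.0369). It was well above background on 24 of the 53 arrays and on 1 of the 6 corn oil arrays, with a corn oil mean of -8.47 ± 0.89 (SD, log2 relative to the 75th percentile). By group its log2 fold change was 1.60 (SE 0.37) in DEHP 30, 1.83 (SE 0.37) in DEHP 300, 1.74 (SE 0.39) in DINCH 30, 1.70 (SE 0.37) in DINCH 300, 1.12 (SE 0.37) in BDB 30, 1.60 (SE 0.37) in BDB 300, 1.91 (SE 0.37) in DOS 30 and 0.79 (SE 0.37) in DOS 300, and it passed in none of these comparisons. The corn oil level rests on signals that were mostly not well above background, so the size of these differences is uncertain. With signal required on all arrays, a filter that leaves Mogat3 out, the count of genes passing was 0. It was 0 with slide, scan day or replicate number as a block, with a normexp background correction and without slide 7. It was also 0 without corn oil replicate 2, 3, 4 or 5, DEHP 30 replicate 2 or 3, DEHP 300 replicate 4 or 5, DINCH 30 replicate 1, 3 or 6, DINCH 300 replicate 3, BDB 30 replicate 3 or 6, BDB 300 replicate 3 or 4, DOS 30 replicate 2 or 4, or DOS 300 replicate 1, 2 or 5.

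Genes of testosterone synthesis did not pass in any exposed group. The log2 fold change of Star, which moves cholesterol into mitochondria, ranged over the 8 comparisons from -0.55 to -0.04 (below 0 in 8 of 8, smallest adjusted p = 0.498). Hsd3b1, a steroid dehydrogenase, ranged from -0.54 to -0.06 (below 0 in 8 of 8, smallest adjusted p = 0.301), and Insl3, a peptide hormone of Leydig cells, from -0.29 to -0.07 (below 0 in 8 of 8, smallest adjusted p = 0.624). For Hsd3b1, BDB 30 replicate 2 and DOS 30 replicate 4 lay -0.856 and -0.689 from the medians of their groups' other arrays. The range of Cyp17a1 was -0.46 to 0.07 (below 0 in 7 of 8, smallest adjusted p = 0.656), that of Cyp11a1, which cleaves the cholesterol side chain, -0.41 to 0.05 (below 0 in 6 of 8, smallest adjusted p = 0.551), and that of the lipoprotein receptor gene Scarb1 -0.39 to 0.04 (below 0 in 7 of 8, smallest adjusted p = 0.377). Lhcgr, the luteinizing hormone receptor gene, ranged from -0.45 to 0.11 (below 0 in 7 of 8, smallest adjusted p = 0.65) and Hsd17b3 from -0.24 to 0.28 (below 0 in 3 of 8, smallest adjusted p = 0.914). All comparisons share the same 6 corn oil arrays, so values on 1 side of 0 across exposures are not independent.

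Gene lists were tested with limma's camera at a preset correlation between genes. This setting takes the members of a list as nearly independent. Its p therefore does not measure the spread between animals, which the SE between arrays does. A list can pass with a shift no larger than that SE, as matrix genes did in DEHP 300 (-0.17 ± 0.17). Lists described below as lower or higher are so by this test. Of 240 tests (30 lists in 8 comparisons), 28 passed, 23 lower and 5 higher than in corn oil. With an estimated correlation 0 passed (smallest adjusted p = 0.646, 12 tests at an unadjusted p under 0.05), and with fry 0 passed (smallest adjusted p = 0.762, 12 at an unadjusted p under 0.05). Shuffled group labels gave as many calls in 28 of 100 draws, the real labels included, and in 34 of 100 with labels shuffled within slides. In 5 simulated runs that lowered the interferon list by 0.5 in DEHP 300 alone, 6 to 26 of the other tests, where nothing was shifted, passed in a run at the preset correlation and 0 with an estimated one. The list itself passed in 5 at either, but that shift is larger than any interferon shift seen here, and smaller ones were not simulated. Over all genes, 0 members of the called lists passed on their own. Adjusted over the list alone, 1 Leydig gene passed in DEHP 30, 1 gene of the fat and mesothelium list and 5 interferon genes passed in DOS 300, and 0 passed in the other called tests. Those lists were called from the same values, so members that passed within them are not separate evidence. The lists overlap: 11 of the 15 Leydig markers and 7 of the steroidogenesis genes belong to another list as well, among them Star, Hsd3b1 and Cyp17a1 in both of these, so their calls are not separate evidence.

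**Figure D2:**
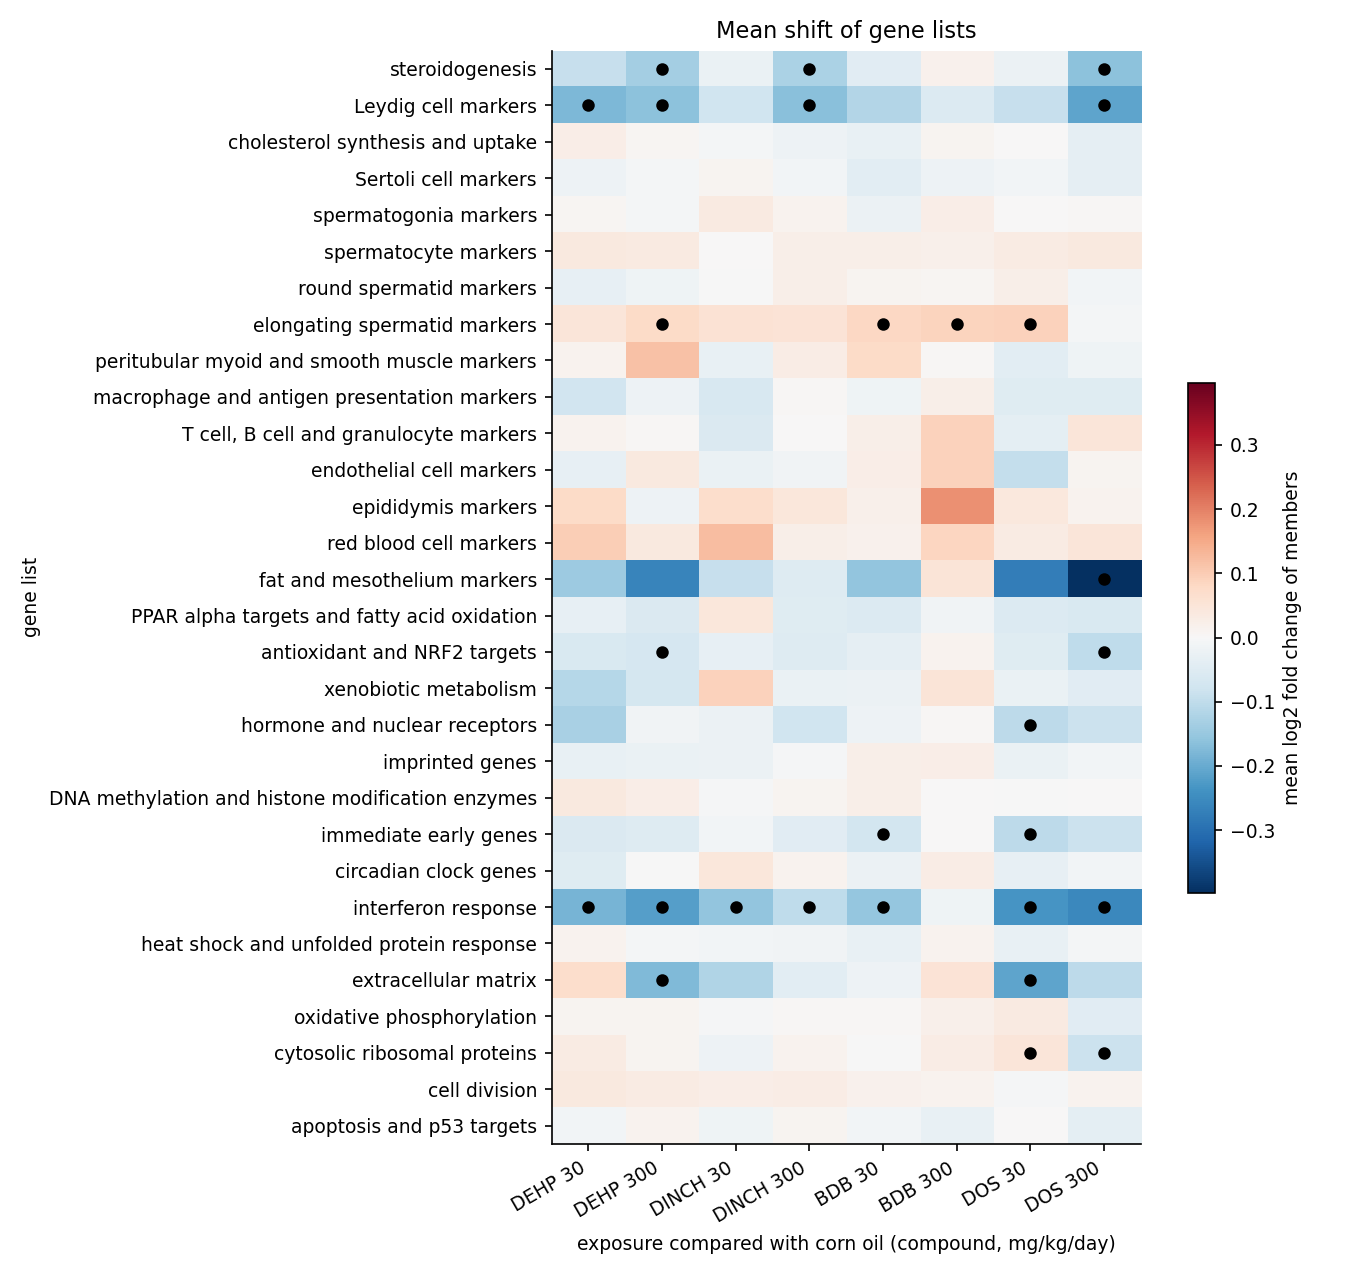
Colour gives the mean log2 fold change of the measured members of each gene list (vertical axis) in each exposure against corn oil (horizontal axis). Black dots mark the 28 tests that passed with camera at a preset correlation, of which 0 passed with an estimated correlation.

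DEHP 30 had lower Leydig cell markers and interferon response genes by camera at the preset correlation. The Leydig list had a mean log2 shift (± SE between arrays) of -0.18 ± 0.08 (11 of 15 members lower, adjusted p = 0.0062, and adjusted p = 0.646 with an estimated correlation). Its members included Nr4a1, a nuclear receptor of steroidogenic cells, at -0.29 (SE 0.09), Star at -0.55 (SE 0.20, limma adjusted p = 0.772) and the prostaglandin synthase gene Ptgds at -0.26 (SE 0.12), for which corn oil replicate 6 lay 0.432 from the median of the other corn oil arrays. The interferon shift was -0.18 ± 0.11 (24 of 26 members lower, adjusted p = 0.00035, and adjusted p = 0.646 with an estimated correlation). The antiviral genes Oasl2 stood at -0.55 (SE 0.22) and Mx2 at -0.20 (SE 0.09). Among the largest single values, none of which passed, were Nr5a2, a nuclear receptor gene, at -1.97 (SE 0.69), Zg16b at -1.37 (SE 0.41), the phospholipase gene Pla2g5 at -0.99 (SE 0.22) and the T cell receptor subunit gene Cd3e at 0.81 (SE 0.23). The Leydig shift was -0.22 with slide as a block (-0.54 to -0.08 within 4 slides) and -0.17 with scan day as a block (-0.29 to -0.04 within 2 days). The interferon shift was -0.23 with slide as a block (-0.57 to 0.16 within 4 slides) and -0.19 with scan day as a block (-0.35 to 0.13 within 2 days). The Leydig call was lost without corn oil replicate 5 or DEHP 30 replicate 3 or 5 (range without 1 array -0.23 to -0.14, highest adjusted p = 0.0856). The interferon call was lost without DEHP 30 replicate 5 (range without 1 array -0.26 to -0.10, highest adjusted p = 0.0792), and its shift was -0.10 with a normexp background correction, where it passed.

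In DEHP 300, interferon, Leydig, steroidogenic, matrix and antioxidant genes were lower and elongating spermatid genes higher by the same test. Interferon genes shifted by -0.22 ± 0.11 (24 of 26 members lower, adjusted p = 6.07e-07, and adjusted p = 0.646 with an estimated correlation). Isg15, a ubiquitin-like antiviral protein gene, stood at -0.66 (SE 0.27), Irf7 at -0.52 (SE 0.26) and the immunoproteasome gene Psmb8 at -0.34 (SE 0.18). Leydig markers shifted by -0.16 ± 0.08 (11 of 15 members lower, adjusted p = 0.00194, and adjusted p = 0.646 with an estimated correlation) and steroidogenesis by -0.14 ± 0.08 (11 of 16 members lower, adjusted p = 0.00499, and adjusted p = 0.646 with an estimated correlation). Hsd3b1 stood at -0.40 (SE 0.20), Cyp17a1 at -0.42 (SE 0.26) and Star at -0.37 (SE 0.20). Extracellular matrix genes shifted by -0.17 ± 0.17 (19 of 22 members lower, adjusted p = 0.000372, and adjusted p = 0.721 with an estimated correlation). The collagen genes Col6a2 stood at -0.41 (SE 0.23) and Col3a1 at -0.46 (SE 0.35). Fat and mesothelium markers moved with them by -0.26 ± 0.23 (adjusted p = 0.0592) without passing, and corn oil replicate 6 was the highest corn oil array in both lists. Antioxidant genes shifted by -0.07 ± 0.05 (21 of 30 members lower, adjusted p = 0.0483, and adjusted p = 0.727 with an estimated correlation). The peroxiredoxin gene Prdx3 stood at -0.26 (SE 0.13). Elongating spermatid markers shifted by 0.08 ± 0.05 (19 of 21 members higher, adjusted p = 0.0027, and adjusted p = 0.73 with an estimated correlation). The transition protein gene Tnp2 stood at 0.19 (SE 0.12) and Hspb9 at 0.24 (SE 0.08). Single genes that did not pass included Upk3bl1 at 1.03 (SE 0.26), Tmc2 at -1.40 (SE 0.51), the prostaglandin-degrading enzyme gene Hpgd at -0.76 (SE 0.26), with replicate 3 0.819 from the median of the others, and the interferon-induced gene Rtp4 at -0.71 (SE 0.19, limma adjusted p = 1).

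Batch and single animals bore on the DEHP 300 lists as follows. With slide and then scan day as a block, and with the range within 5 slides and 3 days in parentheses, the shifts were -0.25 (-0.37 to 0.02) and -0.22 (-0.36 to -0.11) for interferon genes. They were -0.19 (-0.43 to -0.08) and -0.16 (-0.26 to -0.11) for Leydig markers, -0.16 (-0.39 to -0.02) and -0.14 (-0.29 to -0.01) for steroidogenesis. They were -0.22 (-0.91 to 0.26) and -0.18 (-0.27 to 0.09) for matrix, -0.08 (-0.21 to -0.01) and -0.06 (-0.10 to -0.05) for antioxidant genes. They were 0.08 (-0.07 to 0.29) and 0.08 (-0.07 to 0.17) for elongating spermatids. The antioxidant call ended with scan day as a block (adjusted p = 0.0794), with no filter or a stricter filter on dim probes, with every probe on its own, with array weights and without slide 7. That of steroidogenesis ended with no filter on dim probes and without slide 7. The interferon shift was -0.13 with normexp and the spermatid shift 0.04 with quantile normalization, and both passed. The interferon call held without each array in turn. The Leydig call was lost without DEHP 300 replicate 1 (range without 1 array -0.22 to -0.10, highest adjusted p = 0.0529). The matrix call was lost without corn oil replicate 6 (range without 1 array -0.26 to -0.04, highest adjusted p = 0.42). The spermatid call was lost without corn oil replicate 6 or DEHP 300 replicate 1 (range without 1 array 0.05 to 0.10, highest adjusted p = 0.0745). The steroidogenesis call was lost without corn oil replicate 3 or 5 or DEHP 300 replicate 1 or 4 (range without 1 array -0.18 to -0.07, highest adjusted p = 0.103). The antioxidant call was lost without corn oil replicate 3, 5 or 6 or DEHP 300 replicate 1, 4 or 6 (range without 1 array -0.09 to -0.04, highest adjusted p = 0.275).

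In DINCH 30, interferon response genes were the list to pass, with a shift of -0.16 ± 0.11 (21 of 26 members lower, adjusted p = 0.000527, and adjusted p = 0.646 with an estimated correlation). Irf7, a regulator of interferon genes, stood at -0.50 (SE 0.28), Oasl2 at -0.39 (SE 0.23) and Usp18 at -0.26 (SE 0.15). The largest single values, none of which passed, included Nxnl1 at 1.63 (SE 0.49), Upk3bl1 at 1.15 (SE 0.27) and Pard3b at 1.12 (SE 0.34). Hsd3b3, a hydroxysteroid dehydrogenase gene, stood at -2.67 (SE 0.87, limma adjusted p = 1), with an SD of 4.48 in DINCH 30, where replicate 5 lay -10.2 from the median of the others, against 0.38 in corn oil. The interferon shift was -0.13 with slide as a block (-0.26 to -0.12 within 4 slides) and -0.15 with scan day as a block (-0.21 to 0.02 within 3 days), and the call held without each array in turn. With a normexp background correction the shift was -0.01 (adjusted p = 0.0402).

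In DINCH 300, Leydig, steroidogenic and interferon genes were lower by camera at the preset correlation. Leydig markers shifted by -0.17 ± 0.08 (14 of 15 members lower, adjusted p = 0.00194, and adjusted p = 0.646 with an estimated correlation) and steroidogenesis by -0.13 ± 0.08 (12 of 16 members lower, adjusted p = 0.01, and adjusted p = 0.646 with an estimated correlation). Cyp17a1 stood at -0.46 (SE 0.26), Hsd3b1 at -0.40 (SE 0.20), Cyp11a1 at -0.38 (SE 0.25) and Scarb1 at -0.29 (SE 0.17). Interferon genes shifted by -0.10 ± 0.11 (20 of 26 members lower, adjusted p = 0.00913, and adjusted p = 0.73 with an estimated correlation). Parp9 stood at -0.31 (SE 0.18), with replicate 1 -0.932 from the median of the others. Single genes that did not pass included Vps37d at -0.63 (SE 0.14, limma adjusted p = 0.646), Stk32b at -0.64 (SE 0.23), Veph1 at -0.55 (SE 0.16) and Ugt2b1, a glucuronosyltransferase gene, at 1.12 (SE 0.34), with replicate 3 3.03 from the median of the others. Ugt2b1 was well above background on 2 of the 6 corn oil and 3 of the 6 DINCH 300 arrays, so the size of its change is uncertain. The Leydig shift was -0.16 with slide as a block (-0.36 to -0.01 within 5 slides) and -0.17 with scan day as a block (-0.31 to -0.02 within 3 days). That of steroidogenesis was -0.13 with slide as a block (-0.32 to -0.02 within 5 slides) and -0.14 with scan day as a block (-0.23 to 0.00 within 3 days). That of interferon genes was -0.08 with slide as a block (-0.44 to 0.14 within 5 slides) and -0.09 with scan day as a block (-0.16 to 0.07 within 3 days). The Leydig call was lost without DINCH 300 replicate 1 (range without 1 array -0.19 to -0.13, highest adjusted p = 0.0766). The steroidogenesis call was lost without corn oil replicate 3 or 5 or DINCH 300 replicate 1 or 6 (range without 1 array -0.16 to -0.09, highest adjusted p = 0.13). The interferon call was lost without corn oil replicate 1 or 6 or DINCH 300 replicate 1 (range without 1 array -0.14 to -0.06, highest adjusted p = 0.133). With array weights the interferon call ended, and with no filter on dim probes that of steroidogenesis, at -0.08. With normexp the interferon shift was -0.06 and passed.

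In BDB 30, elongating spermatid markers were higher and interferon and immediate early genes lower. The spermatid list shifted by 0.08 ± 0.05 (21 of 21 members higher, adjusted p = 6.92e-05, and adjusted p = 0.646 with an estimated correlation). Akap3, an anchoring protein gene of the sperm tail, stood at 0.12 (SE 0.06), with corn oil replicate 4 -0.47 from the median of the other corn oil arrays, and Tnp2 at 0.20 (SE 0.12). Interferon genes shifted by -0.15 ± 0.11 (21 of 26 members lower, adjusted p = 0.000246, and adjusted p = 0.646 with an estimated correlation). Irf1 stood at -0.24 (SE 0.12) and Psmb8 at -0.33 (SE 0.18). Immediate early genes, which respond within minutes to stimulation, shifted by -0.07 ± 0.05 (16 of 22 members lower, adjusted p = 0.0483, and adjusted p = 0.646 with an estimated correlation). Jund stood at -0.11 (SE 0.08) and Btg2 at -0.20 (SE 0.14). Single genes that did not pass included the complement gene C3 at -1.03 (SE 0.34), the cytokine gene Il24 at -1.22 (SE 0.44) and Pimreg at 0.77 (SE 0.28, limma adjusted p = 1). The spermatid shift was 0.08 with slide as a block (-0.03 to 0.17 within 5 slides) and 0.07 with scan day as a block (0.02 to 0.09 within 3 days). That of interferon genes was -0.15 with slide as a block (-0.57 to -0.02 within 5 slides) and -0.15 with scan day as a block (-0.21 to 0.02 within 3 days). That of immediate early genes was -0.07 with slide as a block (-0.26 to 0.11 within 5 slides) and -0.08 with scan day as a block (-0.13 to 0.02 within 3 days). The spermatid call held without each array in turn, the interferon call was lost without BDB 30 replicate 2 (range without 1 array -0.19 to -0.07, highest adjusted p = 0.107), and the immediate early call was lost under normexp, quantile normalization, median centring, a stricter filter on dim probes, only the groups compared, array weights and the deposited value table. Its shift was -0.01 under normexp and -0.05 with the stricter filter. It was also lost without corn oil replicate 4, 5 or 6 or BDB 30 replicate 2, 3, 4 or 5 (range without 1 array -0.10 to -0.03, highest adjusted p = 0.576). The interferon shift was -0.08 with normexp and the spermatid shift 0.04 with quantile normalization, and both passed.

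In BDB 300, elongating spermatid markers were the list to pass, with a shift of 0.09 ± 0.05 (19 of 21 members higher, adjusted p = 0.00035, and adjusted p = 0.711 with an estimated correlation). Akap3 stood at 0.13 (SE 0.06), Oaz3 at 0.13 (SE 0.07) and the outer dense fibre gene Odf2 at 0.16 (SE 0.08). Interferon genes had a mean shift of -0.02 and Leydig markers of -0.05, which did not pass (adjusted p = 0.652 and 0.286). Single genes that did not pass included Rnase1l1 at 1.77 (SE 0.54), with corn oil replicate 2 2.19 from the median of the other corn oil arrays, Gch1, whose enzyme starts tetrahydrobiopterin synthesis, at -0.68 (SE 0.22) and Fn3krp at -0.26 (SE 0.08, limma adjusted p = 1), with replicate 5 -0.257 from the median of the others. The spermatid shift was 0.09 with slide as a block (0.01 to 0.10 within 5 slides) and 0.09 with scan day as a block (0.01 to 0.12 within 3 days), and the call held without each array in turn. It was 0.04 with quantile normalization, where it passed.

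In DOS 30, interferon, matrix, immediate early and receptor genes were lower and elongating spermatid and ribosomal protein genes higher. Interferon genes shifted by -0.23 ± 0.11 (23 of 26 members lower, adjusted p = 1.51e-06, and adjusted p = 0.646 with an estimated correlation). Rsad2 stood at -0.69 (SE 0.22), Oas1a at -0.70 (SE 0.31) and Oasl2 at -0.58 (SE 0.22), all antiviral genes, with corn oil replicate 3 -0.812 from the other corn oil arrays in Rsad2. Spermatid markers shifted by 0.09 ± 0.05 (20 of 21 members higher, adjusted p = 0.000109, and adjusted p = 0.646 with an estimated correlation). Akap3 stood at 0.18 (SE 0.06). Matrix genes shifted by -0.21 ± 0.17 (21 of 22 members lower, adjusted p = 0.000246, and adjusted p = 0.721 with an estimated correlation). The proteoglycan gene Bgn stood at -0.42 (SE 0.15). Fat and mesothelium markers moved with the matrix list by -0.27 ± 0.23 (adjusted p = 0.103) and endothelial markers by -0.09 ± 0.08 (adjusted p = 0.182), and neither passed. Immediate early genes shifted by -0.11 ± 0.05 (16 of 22 members lower, adjusted p = 0.00426, and adjusted p = 0.646 with an estimated correlation), although their mean was 0.0031 under a normexp background correction, and hormone and nuclear receptors by -0.11 ± 0.04 (22 of 33 members lower, adjusted p = 0.0398, and adjusted p = 0.646 with an estimated correlation). Rxrg stood at -0.42 (SE 0.17). Ribosomal proteins shifted by 0.05 ± 0.04 (33 of 38 members higher, adjusted p = 0.0137, and adjusted p = 0.912 with an estimated correlation). Rpl38 stood at 0.13 (SE 0.07). Single genes that did not pass included Ppp3ca, a calcineurin subunit gene, at 1.22 (SE 0.33), Upk3bl1 at 1.14 (SE 0.26, limma adjusted p = 0.6), Ogn at -1.23 (SE 0.38), with corn oil replicate 6 1.15 from the other corn oil arrays, and C3 at -0.97 (SE 0.34).

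With slide and then scan day as a block, and with the range within 4 slides and 3 days in parentheses, the DOS 30 shifts were -0.23 (-0.50 to -0.08) and -0.23 (-0.31 to -0.13) for interferon genes. They were 0.09 (0.01 to 0.24) and 0.09 (0.00 to 0.14) for spermatid markers, -0.21 (-0.40 to -0.03) and -0.22 (-0.38 to 0.20) for matrix. They were -0.08 (-0.20 to 0.06) and -0.10 (-0.11 to -0.08) for immediate early genes, -0.09 (-0.20 to 0.05) and -0.10 (-0.20 to -0.04) for receptors. They were 0.04 (-0.06 to 0.12) and 0.05 (0.02 to 0.06) for ribosomal proteins. The ribosomal call ended with slide as a block (adjusted p = 0.201), and under normexp and quantile normalization, the receptor call under both of these, with no filter on dim probes and with array weights, the immediate early call under normexp, and the spermatid call under quantile normalization. Under quantile normalization the spermatid shift was 0.03 and the ribosomal shift 0.01, which was 0.03 with the deposited value table. Under normexp the interferon shift was -0.09 and passed, and the receptor shift was -0.01. The interferon and spermatid calls held without each array in turn. The matrix call was lost without corn oil replicate 6 (range without 1 array -0.29 to -0.07, highest adjusted p = 0.301). The immediate early call was lost without corn oil replicate 6 (range without 1 array -0.13 to -0.06, highest adjusted p = 0.176). The receptor call was lost without corn oil replicate 3, 5 or 6 or DOS 30 replicate 3, 4 or 5 (range without 1 array -0.12 to -0.09, highest adjusted p = 0.17). The ribosomal call was lost without corn oil replicate 1, 4 or 6 or DOS 30 replicate 1, 2 or 3 (range without 1 array 0.04 to 0.06, highest adjusted p = 0.11).

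In DOS 300, interferon, ribosomal, Leydig, steroidogenic, antioxidant, and fat and mesothelium genes were lower. Interferon genes shifted by -0.26 ± 0.11 (22 of 26 members lower, adjusted p = 4.01e-05, and adjusted p = 0.646 with an estimated correlation). Mx2 stood at -0.27 (SE 0.09) and Oas1b at -0.16 (SE 0.05). Outside that list Ubd, a ubiquitin-like gene, stood at -1.18 (SE 0.42), Ifi27l2b at -0.93 (SE 0.29) and the peptide transporter gene Tap2 at -0.96 (SE 0.28, limma adjusted p = 0.237), and none of these passed. Ribosomal proteins shifted by -0.08 ± 0.04 (31 of 38 members lower, adjusted p = 4.8e-05, and adjusted p = 0.721 with an estimated correlation). Rpl15 stood at -0.26 (SE 0.08), while the other probes of Rpl27 and Rpl6 had the opposite direction. Leydig markers shifted by -0.21 ± 0.08 (13 of 15 members lower, adjusted p = 0.0483, and adjusted p = 0.646 with an estimated correlation) and steroidogenesis by -0.16 ± 0.08 (12 of 16 members lower, adjusted p = 0.0458, and adjusted p = 0.721 with an estimated correlation). Hsd3b1 stood at -0.54 (SE 0.20, limma adjusted p = 0.301) and the mitochondrial electron donors Fdxr at -0.21 (SE 0.07) and Fdx1 at -0.14 (SE 0.06). Fat and mesothelium markers shifted by -0.40 ± 0.23 (11 of 12 members lower, adjusted p = 0.0353, and adjusted p = 0.646 with an estimated correlation). Wt1 stood at -0.36 (SE 0.08), a direction that its other 2 probes did not share. Antioxidant genes shifted by -0.10 ± 0.05 (22 of 30 members lower, adjusted p = 0.0483, and adjusted p = 0.728 with an estimated correlation). Gpx4 stood at -0.24 (SE 0.09). The largest single value was Tent5b at 2.97 (SE 0.95), which was well above background on 2 of the 6 corn oil arrays, with replicate 3 3.31 from the median of the others, and did not pass.

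With slide and then scan day as a block, and with the range within 4 slides and 3 days in parentheses, the DOS 300 shifts were -0.25 (-0.42 to -0.07) and -0.25 (-0.32 to -0.14) for interferon genes. They were -0.08 (-0.16 to -0.02) and -0.09 (-0.14 to -0.07) for ribosomal proteins, -0.22 (-0.37 to -0.16) and -0.21 (-0.27 to -0.12) for Leydig markers. They were -0.18 (-0.36 to -0.10) and -0.17 (-0.19 to -0.13) for steroidogenesis, -0.48 (-1.89 to 0.01) and -0.37 (-0.57 to 0.21) for fat and mesothelium. They were -0.10 (-0.31 to -0.04) and -0.09 (-0.12 to 0.00) for antioxidant genes. The calls of fat and mesothelium and of antioxidant genes ended with scan day as a block (adjusted p = 0.0547 and 0.0794), and those of ribosomal, Leydig, steroidogenic and antioxidant genes with a normexp background correction. With no filter on dim probes and with array weights the Leydig, steroidogenesis, antioxidant, and fat and mesothelium calls ended. The Leydig call also ended with a stricter filter, with the deposited value table and without slide 7, that of steroidogenesis without slide 7, and that of fat and mesothelium with a stricter filter and with every probe on its own. The DOS 300 arrays also had the highest mean 75th percentile of signal before scaling, at 1630 ± 223 (SD) against 1349 ± 153 in corn oil and 1302 ± 50.8 in DOS 30. The interferon and ribosomal calls held without each array in turn. The Leydig call was lost without corn oil replicate 3, 5 or 6 or DOS 300 replicate 3, 4 or 5 (range without 1 array -0.23 to -0.17, highest adjusted p = 0.206). The steroidogenesis call was lost without corn oil replicate 3, 5 or 6 or DOS 300 replicate 3, 4 or 5 (range without 1 array -0.19 to -0.13, highest adjusted p = 0.203). The fat and mesothelium call was lost without corn oil replicate 5 or 6 or DOS 300 replicate 1 or 4 (range without 1 array -0.51 to -0.14, highest adjusted p = 0.543). The antioxidant call was lost without corn oil replicate 3, 5 or 6 or DOS 300 replicate 3, 4 or 5 (range without 1 array -0.12 to -0.08, highest adjusted p = 0.259).

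**Figure D3:**
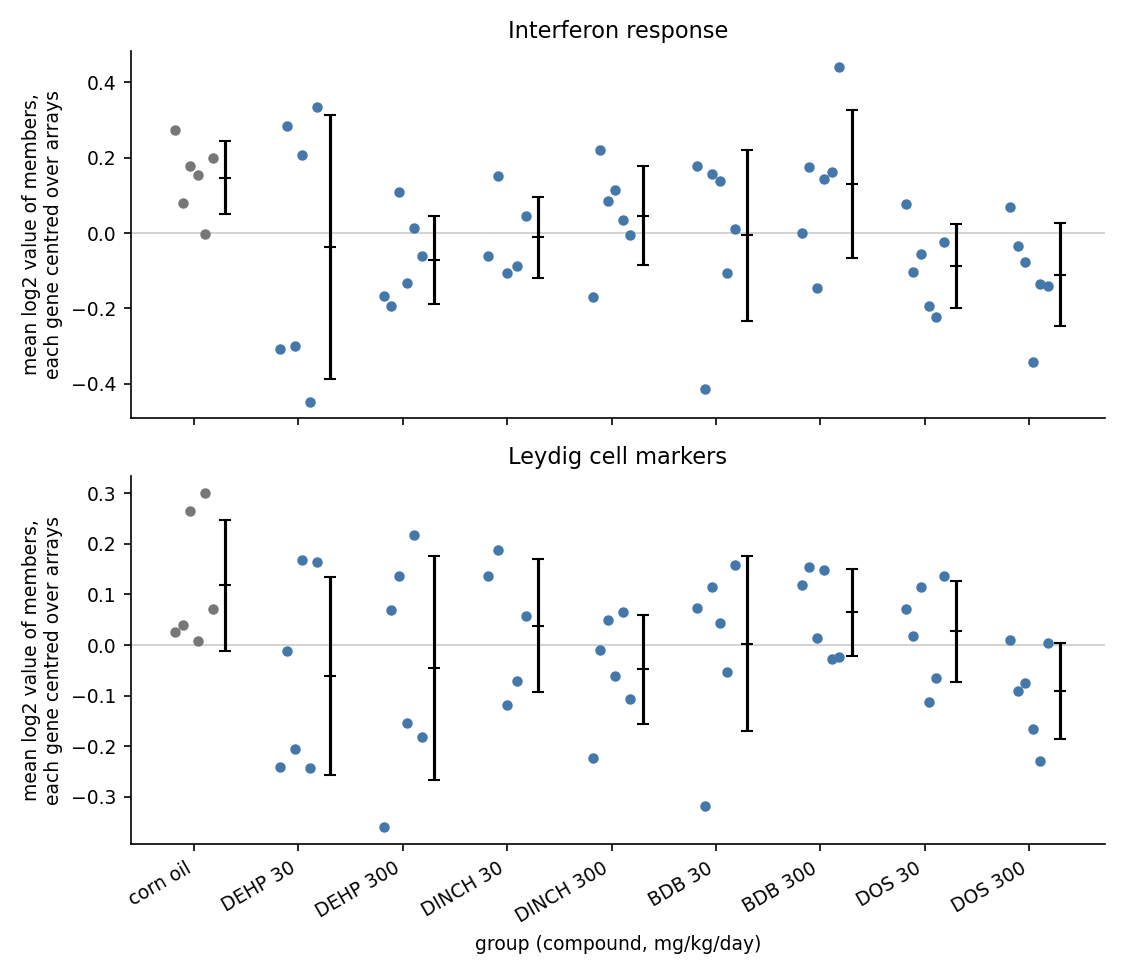
Points are single arrays, with the mean log2 value of the members of the interferon list (top) and the Leydig list (bottom), each gene centred over all arrays (vertical axis), by group (horizontal axis). Bars show the group mean and SD of 6 arrays, or 5 in DINCH 30.

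The other 20 lists did not pass in any comparison with corn oil. The mean log2 shift of PPAR alpha targets and fatty acid oxidation genes, which phthalates induce in rodent liver, ranged over the 8 comparisons from -0.06 to 0.05, that of cholesterol synthesis and uptake from -0.04 to 0.03 and that of xenobiotic metabolism from -0.11 to 0.09. Among germ cells, spermatogonia markers ranged from -0.02 to 0.04, spermatocyte markers from 0.00 to 0.04 and round spermatid markers from -0.03 to 0.02. Sertoli cell markers ranged from -0.04 to 0.01, peritubular myoid markers from -0.04 to 0.12, macrophage markers from -0.08 to 0.02, lymphocyte and granulocyte markers from -0.06 to 0.09 and endothelial markers from -0.09 to 0.09. Epididymis markers ranged from -0.02 to 0.18 and red blood cell markers from 0.02 to 0.12. Imprinted genes ranged from -0.03 to 0.03, enzymes of DNA methylation and histone modification from -0.01 to 0.04 and circadian clock genes from -0.05 to 0.05. Heat shock genes ranged from -0.03 to 0.01, oxidative phosphorylation from -0.04 to 0.04, cell division from 0.00 to 0.04 and apoptosis and p53 targets from -0.04 to 0.01.

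Between the doses of a compound, ribosomal protein and oxidative phosphorylation genes were lower in DOS 300 than in DOS 30 by camera at the preset correlation. Chance was not excluded for the list calls between doses or compounds. Shuffled group labels gave as many calls in 59 of 100 draws, the real labels included, and in 73 of 100 within slides. Ribosomal proteins differed by -0.13 ± 0.04 (36 of 38 members lower, adjusted p = 1.47e-09, and adjusted p = 0.982 with an estimated correlation) and oxidative phosphorylation by -0.08 ± 0.03 (32 of 40 members lower, adjusted p = 0.00076, and adjusted p = 0.982 with an estimated correlation). Adjusted over the list alone, 16 ribosomal and 1 oxidative phosphorylation members passed, against 0 over all genes. The lists were called from the same values, so the members that passed within them are not separate evidence. Elongating spermatid markers differed by -0.10 ± 0.05 (15 of 21 members lower, adjusted p = 0.0122, and adjusted p = 0.982 with an estimated correlation) and by 0.03, in the other direction, under quantile normalization. Matrix genes were lower in DEHP 300 than in DEHP 30 by -0.25 ± 0.17 (21 of 22 members lower, adjusted p = 1.54e-06, and adjusted p = 0.982 with an estimated correlation), and interferon genes higher in BDB 300 than in BDB 30 by 0.14 ± 0.11 (22 of 26 members higher, adjusted p = 0.00357, and adjusted p = 0.982 with an estimated correlation). The ribosomal difference was -0.12 with slide as a block (-0.20 to -0.10 within 4 slides) and -0.13 with scan day as a block (-0.16 to -0.13 within 3 days). That of oxidative phosphorylation was -0.07 with slide as a block (-0.12 to -0.05 within 4 slides) and -0.08 with scan day as a block (-0.09 to -0.08 within 3 days). That of matrix genes for DEHP was -0.20 with slide as a block (-0.71 to 0.44 within 5 slides) and -0.23 with scan day as a block (-0.22 to -0.22 within 2 days), and that of fat and mesothelium markers, which did not pass, -0.12 ± 0.23 (adjusted p = 0.792). Limma called 0 single genes between doses, with 833 at an unadjusted p under 0.05 for DEHP, 624 for DINCH, 454 for BDB and 3052 for DOS (smallest adjusted p = 0.0663). Over the 4 dose contrasts the calls were 325 without DOS 30 replicate 4 and 35 without DOS 300 replicate 4. They were 746 with array weights, 42 with normexp and 1 to 4 under 6 other settings. The 75th percentile of signal before scaling also differed between DOS 300 (1630 ± 223, SD) and DOS 30 (1302 ± 50.8). With its log2 value as a covariate 1239 genes in place of 3028 reached an unadjusted p under 0.05 between them, so these list differences are not told apart from signal strength. The matrix call was lost without DEHP 30 replicate 4 (range without 1 array -0.35 to -0.02, highest adjusted p = 0.417). The BDB interferon call was lost without BDB 30 replicate 2 or BDB 300 replicate 6 (range without 1 array 0.05 to 0.19, highest adjusted p = 0.389). The spermatid call was lost without DOS 300 replicate 3 (range without 1 array -0.12 to -0.08, highest adjusted p = 0.0709), and it ended with quantile normalization. Those of spermatids, ribosomal proteins and oxidative phosphorylation ended with a normexp background correction. With quantile normalization the ribosomal difference was -0.07 and that of oxidative phosphorylation -0.05, with array weights that of matrix genes for DEHP was -0.16, and with normexp that of interferon genes for BDB was 0.09, and all of these passed.

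Between compounds at 300 mg/kg/day, by camera at the preset correlation, steroidogenic and interferon genes were higher in BDB than in DEHP. By the same test ribosomal proteins were lower in DOS than in each other compound. Shuffled labels gave as many list calls between doses or compounds in 59 of 100 draws, so chance was not excluded. The Leydig list, which overlaps steroidogenesis, did not pass for BDB against DEHP or DINCH. Steroidogenesis was higher in BDB than in DEHP by 0.15 ± 0.08 (14 of 16 members higher, adjusted p = 0.000395, and adjusted p = 0.982 with an estimated correlation) and than in DINCH by 0.15 ± 0.08 (14 of 16 members higher, adjusted p = 0.00246, and adjusted p = 0.982 with an estimated correlation). Interferon genes were higher in BDB than in DEHP by 0.20 ± 0.11 (25 of 26 members higher, adjusted p = 1.54e-06, and adjusted p = 0.982 with an estimated correlation), as were matrix genes by 0.23 ± 0.17 (21 of 22 members higher, adjusted p = 0.00029, and adjusted p = 0.982 with an estimated correlation), with which fat and mesothelium markers moved by 0.31 ± 0.23 (adjusted p = 0.147) without passing. Ribosomal proteins were lower in DOS than in DEHP by -0.10 ± 0.04 (34 of 38 members lower, adjusted p = 5.37e-06, and adjusted p = 0.982 with an estimated correlation), than in DINCH by -0.10 ± 0.04 (35 of 38 members lower, adjusted p = 6.5e-07, and adjusted p = 0.982 with an estimated correlation) and than in BDB by -0.11 ± 0.04 (37 of 38 members lower, adjusted p = 8.8e-08, and adjusted p = 0.982 with an estimated correlation), calls that ended with a normexp background correction. With quantile normalization these were -0.05, -0.06 and -0.06 and passed. Interferon genes were lower in DOS than in BDB by -0.24 ± 0.11 (23 of 26 members lower, adjusted p = 0.000336, and adjusted p = 0.982 with an estimated correlation). With slide and then scan day as a block, and with ranges within slides and days in parentheses, the differences of BDB from DEHP were 0.17 (-0.14 to 0.47) and 0.16 (-0.06 to 0.38) for steroidogenesis, 0.22 (0.05 to 0.43) and 0.20 (0.18 to 0.31) for interferon and 0.25 (-0.30 to 0.88) and 0.24 (0.16 to 0.52) for matrix genes. That of DOS from DEHP in ribosomal proteins was -0.09 (-0.22 to 0.00) and -0.10 (-0.16 to -0.04). The BDB and DEHP difference in steroidogenesis was lost without DEHP 300 replicate 1 (range without 1 array 0.09 to 0.20, highest adjusted p = 0.059) and that in matrix genes without BDB 300 replicate 4 (range without 1 array 0.11 to 0.31, highest adjusted p = 0.33). Limma called 0 single genes at this dose, with 393 at an unadjusted p under 0.05 for DINCH against DEHP, 540 for BDB against DEHP and 2296 for DOS against DEHP. The calls at this dose were 89 with array weights and 1 with normexp. The 75th percentile of signal before scaling was higher in DOS 300 (1630 ± 223, SD) than in DEHP 300 (1347 ± 204), DINCH 300 (1404 ± 143) and BDB 300 (1304 ± 179), so the differences of DOS from them are not told apart from signal strength. The 95% interval of a difference of median spread, without adjustment for the number of genes, reached 0.21 to either side on the log2 scale. Smaller differences were not resolved, and larger ones can also fail after adjustment. The compounds are therefore not shown to act alike.

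Between compounds at 30 mg/kg/day, matrix genes were lower in DOS than in DEHP by -0.28 ± 0.17 (22 of 22 members lower, adjusted p = 6.5e-07, and adjusted p = 0.982 with an estimated correlation), and ribosomal proteins lower in DINCH than in DEHP by -0.05 ± 0.04 (31 of 38 members lower, adjusted p = 0.000153, and adjusted p = 0.982 with an estimated correlation). Ribosomal proteins were higher in DOS than in DINCH by 0.07 ± 0.04 (33 of 38 members higher, adjusted p = 1.54e-05, and adjusted p = 0.982 with an estimated correlation) and than in BDB by 0.05 ± 0.04 (35 of 38 members higher, adjusted p = 0.000415, and adjusted p = 0.982 with an estimated correlation). The matrix difference was -0.18 with slide as a block (-0.50 to 0.15 within 4 slides) and -0.26 with scan day as a block (-0.33 to -0.25 within 2 days), and fat and mesothelium markers differed by -0.13 ± 0.23 (adjusted p = 0.864) without passing. That of ribosomal proteins between DINCH and DEHP was -0.05 with slide as a block (0.02 to 0.14 within 2 slides) and -0.05 with scan day as a block (-0.08 to 0.07 within 2 days). On each of the 2 slides that held both groups, ribosomal proteins were thus higher in DINCH, against the direction of the call. The matrix call was lost without DEHP 30 replicate 4 (range without 1 array -0.39 to -0.06, highest adjusted p = 0.277), and the ribosomal calls of DINCH against DEHP without DINCH 30 replicate 4 (range without 1 array -0.09 to 0.00, highest adjusted p = 0.354) and of DOS against DINCH without DINCH 30 replicate 4 (range without 1 array 0.02 to 0.10, highest adjusted p = 0.18). The ribosomal call of DOS against BDB ended with normexp and without slide 7. That of DINCH against DEHP was -0.08 with median centring, -0.03 with array weights and -0.03 without slide 7, and that of DOS against DINCH 0.04 with quantile normalization, and all of these passed. Limma called 0 single genes, with 1388 at an unadjusted p under 0.05 for DINCH against DEHP, 982 for BDB against DEHP and 1034 for DOS against DEHP. The calls at this dose were 1 with slide as a block and 2 with only the groups compared. Between doses or compounds, 41 of 480 list tests passed (17 higher, 24 lower), 0 with an estimated correlation (smallest adjusted p = 0.982) and 0 with fry (smallest adjusted p = 0.87). Shuffled group labels gave at least 41 calls in 59 of 100 draws, the real labels included, and in 73 of 100 within slides. The calls given here are those at an adjusted p under 0.001 and a few others, picked after their values were seen.

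The log2 changes of different exposures correlated across genes within the range of simulated unchanged groups that share 1 control group, with the processing used here. Over 16 pairs of exposures r across 22029 genes, which are not independent replicates, was 0.404 to 0.554. Unchanged groups were simulated by shuffling the deviations of all arrays from their group means, with 1 shared shuffled set in place of corn oil. They gave mean r of 0.471 to 0.508, and 0 of the 16 pairs lay outside the simulated range in r or in covariance. For the doses of DEHP the covariance was 0.0187 against 0.0192 simulated, for those of DINCH 0.0175 against 0.0194, for those of BDB 0.0162 against 0.0189 and for those of DOS 0.0157 against 0.0191. With each exposure of a pair set against its own 3 corn oil arrays, mean r was -0.073 to 0.015. With normexp, for which no unchanged groups were simulated, r was 0.115 for the doses of DOS (0.404 without it), 0.315 for BDB 300 and DOS 300 (0.453), 0.326 for DEHP 30 and DINCH 30 (0.437), 0.354 for DINCH 300 and DOS 300 (0.521) and at least 0.436 for the other pairs. With the other ways of processing r was 0.385 to 0.573.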

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

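No test of a cause was run for the values in this part, before or after they were seen. Each is the distance of 1 array from the median of the other arrays of its group, of 6 arrays or of 5 in DINCH 30. In each case the gap to the nearest array, divided by the range of the group, was above Dixon's 95% critical value. Chance alone sets an array apart in about 1 of 20 groups. Of 331 combinations of a named gene and a group, 30 had such an array, where a rate of 1 in 20 gives 16.6. Of 38 combinations of a gene list and a group it was 1, where that rate gives 1.9, and of 18 combinations of an array measure and a group it was 3, where it gives 0.9. Apart from the steroidogenic genes, the named genes were picked from the same values, and a single outlying array can enlarge a change. The 16.6 is therefore not the chance level for genes so picked, and no conclusion is drawn from the 30. The arrays set apart most often were corn oil replicate 6 with 5, DOS 30 replicate 4 with 4, corn oil replicate 3 with 4 and corn oil replicate 4 with 3.

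Genes of steroid synthesis stood apart on single arrays of 4 exposed groups. Hsd3b3 lay -10.2 on the log2 scale from the other arrays in DINCH 30 replicate 5, where its signal was near the floor (-8.976 against a median of 1.264). The distance of Hsd3b1 was -0.856 in BDB 30 replicate 2 and -0.689 in DOS 30 replicate 4, and that of Fdxr was -0.24 in DEHP 300 replicate 4. Among interferon-related genes, DINCH 300 replicate 1 was lower in Parp9 by -0.932 and in Psmb9 by -0.402. Helz2 lay -0.596 from the others in BDB 30 replicate 3 and 1.41 in corn oil replicate 3, where Rsad2 lay -0.812. Among spermatid genes Tnp1 lay -0.296 in DOS 30 replicate 4 and Akap3 -0.47 in corn oil replicate 4.

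Of the other genes in exposed groups, the log2 distance was 1.29 for Adamts18 in DEHP 30 replicate 6, 0.819 for Hpgd in DEHP 300 replicate 3 and 3.03 for Ugt2b1 in DINCH 300 replicate 3. In BDB 300 it was -0.804 for Ecel1 in replicate 3, 0.368 for Ddit4 in replicate 4 and -0.257 for Fn3krp in replicate 5. In DOS 30 replicate 4 it was -1.07 for Rab27b and -1.02 for Orai2, and in DOS 300 replicate 3 it was -0.401 for Rpl6.

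In corn oil, which enters every comparison with an exposure, replicate 6 lay 0.25 from the other arrays in the mean of the immediate early genes. Its distance was 3.5 in Sbp, 1.15 in Ogn, 0.432 in Ptgds and 0.361 in Rarg. Replicate 3 lay 3.31 in Tent5b and -1.28 in Orai2, and replicate 4 lay 4.71 in Klhl38 and 0.718 in Mfsd6. Replicate 1 lay 3.75 in Dapk2 and replicate 2 lay 2.19 in Rnase1l1. Among measures of the arrays themselves, the 75th percentile of the signal before scaling was 299 above the others in DEHP 30 replicate 2 and 341 above them in DINCH 300 replicate 5. The number of spots well above background differed by -2140 in BDB 30 replicate 5.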

How the results depend on the processing

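Leaving out the arrays of slide 7 was chosen after the data were seen; every other alternative was planned. No gene passed limma in the 8 comparisons with corn oil under any planned setting that kept all arrays, nor without slide 7. The F test over the groups gave 0 in each, except with only the groups compared, where it was not run. The count at an unadjusted p under 0.05 ran over these settings from 816 to 1583 for DEHP 30, 543 to 1119 for DEHP 300, 607 to 1499 for DINCH 30, 342 to 774 for DINCH 300, 347 to 879 for BDB 30, 364 to 905 for BDB 300, 691 to 1213 for DOS 30 and 2135 to 3412 for DOS 300. For both doses of DEHP averaged, quantile normalization gave 1 gene. For the average of the 8 exposures the count of 1 gene became 0 with a normexp background correction, with slide or scan day as a fixed block and without slide 7. With signal required on all arrays it was 0 because that filter leaves Mogat3 out. Between doses, the count of 0 became 42 with normexp, 3 with quantile normalization, 1 with no filter on dim probes, 3 with slide as a random block, 1 with only the groups compared, 746 with array weights, 4 with eBayes with trend and robust options and 3 with the deposited value table. Between compounds at 30 mg/kg/day it became 1 with slide as a fixed block and 2 with only the groups compared, and at 300 mg/kg/day 1 with normexp and 89 with array weights. Of the list tests against corn oil, 28 had passed, and 49 did so with normexp, 0 with an estimated correlation and 0 with fry. Over the other settings the count was 21 to 40, with 40 reached without slide 7. Of the 41 list calls between doses or compounds, 0 passed with an estimated correlation and 0 with fry, and the count was 28 to 50 otherwise. The cause was not tested for these differences, except that fewer genes were tested where signal was required on all arrays and fewer arrays where groups or slide 7 were left out.

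Replicate numbers were not taken to pair the arrays, since the labels give them no meaning, although limma found 202 of 22029 genes to differ between numbers at an adjusted p under 0.05, where scan day gave 32 and slide 4209. Of 47 pairs of a corn oil and an exposed array with the same number, 9 had deviations from their group means that correlated over 0.1, and 0 of the 8 comparisons had every pair over 0.1. The mean correlation was 0.03 for the same number and -0.006 for different ones, and 11 exposed arrays correlated best with the corn oil array of their own number. With replicate number as a block the count for the average of the 8 exposures was 0 in place of 1, list calls were 27 against corn oil and 40 between groups, and no other count of single genes at an adjusted p under 0.05 changed, while the count at an unadjusted p under 0.05 rose in all 8 exposures (in DEHP 30 from 1363 to 1481). The calls of immediate early genes in BDB 30 and antioxidant genes in DOS 300 ended with it.

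Leaving out 1 array at a time gave 0 to 1 genes for DEHP 30 (Pla2g5, at -1.19 with adjusted p = 0.0108 without corn oil replicate 1 and at -1.18 with adjusted p = 0.0171 without DEHP 30 replicate 1). It gave 0 to 1 for DEHP 300 (Mogat3, at 2.09 with adjusted p = 0.0253 without corn oil replicate 6 and adjusted p = 0.0271 without DEHP 300 replicate 6) and 0 to 1 for DOS 30 (Mogat3, at 2.17 with adjusted p = 0.0127 without corn oil replicate 6). The range was 0 to 1 for both doses of DEHP (1 without corn oil replicate 1 or 6, DEHP 30 replicate 4 or DEHP 300 replicate 6), of DINCH (1 without corn oil replicate 1 or 6 or DINCH 30 replicate 4) and of BDB (1 without corn oil replicate 2), 0 to 1 for the average of the 8 exposures, and 0 to 0 for the F test and all other comparisons with corn oil. Between doses it was 0 to 325, with 325 without DOS 30 replicate 4, 35 without DOS 300 replicate 4, 5 without DEHP 30 replicate 4, 4 without DINCH 30 replicate 4, 3 without DINCH 300 replicate 1 or 5, 2 without BDB 300 replicate 3 or DOS 300 replicate 3, and 0 otherwise. Between compounds it was 0 to 0 at 30 mg/kg/day and 0 to 3 at 300 mg/kg/day, with 3 without BDB 300 replicate 5. List calls ranged from 20 (without corn oil replicate 5 or 6 or DINCH 300 replicate 1) to 54 (without corn oil replicate 2) against corn oil, and from 32 to 50 between groups.

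Among 5684 values of 213 pairs of a named gene and a comparison, 71 changed sign. The log2 change turned with normexp from -0.85 to 0.0068 for Nab1 and from -0.39 to 0.0871 for Fosl2 in DOS 30, and from 0.67 to -0.0888 for Chrna5 in DOS 300, none of which had passed, and the cause was not tested. Of 1173 list values under alternatives other than leaving out a single array, 286 lost the call and 0 passed in the opposite direction. Signal over background limits the dim genes: Mogat3 was well above background on 24 of 53 arrays.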

Other observations

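The tests with slide as a block, with the 75th percentile of each array as a covariate, of DOS 300 against DOS 30 and of other splits of the samples for all results but DOS 300 and the interferon list were chosen after the result was seen, as were the statistic counted in each split and the shuffles of labels within slides.

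Genes that differed most among the 9 groups did not pass (limma F test, adjusted p = 0.999 for each) and included a chemokine gene and genes of sperm structure and cell division. Cxcl17, the chemokine gene, ranged from -5.27 ± 0.32 (SD, log2 relative to the 75th percentile) in DEHP 300 to -4.60 ± 0.17 in DOS 30. Spag16, a gene of the sperm axoneme, ranged from 2.42 ± 0.07 in DOS 30 to 2.66 ± 0.04 in DOS 300, and Bora, an activator of a mitotic kinase, from -2.31 ± 0.21 in BDB 300 to -1.87 ± 0.12 in DOS 300. DOS 300 was also the lowest group in Zfp410, at -2.68 ± 0.17 against -2.12 ± 0.04 in BDB 30, and in Fam117b, at -1.93 ± 0.06 against -1.70 ± 0.07 in DOS 30, and the highest in Fam83b, at -1.61 ± 0.10 against -1.90 ± 0.08 in corn oil. Corn oil was the lowest group in Mogat3 and in Upk3bl1, at -4.88 ± 0.47 against -3.72 ± 0.33 in DINCH 30. The third principal component held 4.07% of the variance, of which group accounted for 27.5% and slide for 11.7%, and the DOS 300 arrays lay between 9.43 and 16.92 on it, where corn oil arrays lay between -7.95 and 5.05, DOS 30 arrays between -16.11 and 12.86 and DINCH 30 arrays between -9.39 and 26.59. With 9 groups and 8 slides, part of each share arises by chance, and these shares were not tested.

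Interferon response genes passed as lower than in corn oil in 7 of 8 exposures with camera at a preset correlation, and in 0 with an estimated correlation (smallest adjusted p = 0.646). A single corn oil animal as the cause was argued against, since at least 6 comparisons called the list without any 1 corn oil array. Slide as the whole cause was argued against, since the mean shift over the 8 exposures was -0.168 with slide as a block (SE 0.083) against -0.165 without, and the calls at the preset correlation held. Fewer immune cells in the exposed testes stay open, since the lower of the macrophage and lymphocyte shifts was -0.031 (SE 0.067) and the other 0.01. Chance was not excluded: in 8 of 100 splits, the real one included, the list passed in 1 direction in at least 7 comparisons (real 7, highest other 8), and in 3 of 100 with labels shuffled within slides (highest other 7), but at least 1 of the 30 lists did so in 21 and 22 of them, and the exposures, which share the corn oil arrays, remain an untested explanation.

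Leydig cell and steroidogenic genes passed as lower in DEHP 300 and DINCH 300 at the preset correlation (adjusted p = 0.646 with an estimated correlation), and Leydig markers also in DEHP 30 (-0.18) and DOS 300 (-0.21) and steroidogenic genes in DOS 300 (-0.16), which were not weighed. A lower share of all cells outside the germ line would lower the other lists alike. In DEHP 300 the myoid list stood at 0.116 (SE 0.075), barely over 1 SE, with a Leydig minus myoid shift of -0.28 (SE 0.104). This met the rule set beforehand against that cause. The rule takes the highest list, however, and the Sertoli (-0.0093), macrophage (-0.0195) and endothelial (0.0376) lists lay within 1 SE of 0, so the cause stays open. It also stays open in DINCH 300, where the myoid list, the highest, stood at 0.0307 (SE 0.0751) and the Leydig minus myoid shift at -0.197 (SE 0.104). Slide as the whole cause was argued against, with a shift in DINCH 300 of -0.158 with slide as a block (SE 0.081) against -0.166 without and -0.19 in DEHP 300, and both calls at the preset correlation held. A single animal stays open, since the weakest Leydig shift without 1 exposed array was -0.101 against -0.164 with all (SE 0.084) in DEHP 300 and -0.131 against -0.166 in DINCH 300. The steroidogenesis calls of both groups were also lost without corn oil replicate 3 or 5, while the Leydig calls held without each corn oil array. An effect of exposure on Leydig cells may be a candidate explanation but was not told apart from a single animal or from fewer cells outside the germ line. Nor was it told apart from chance, for which no splits were run on this pattern.

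DOS 300 had the most genes at an unadjusted p under 0.05, although its arrays overlapped those of DOS 30 on the third principal component. Against corn oil, 4 of 100 splits, the real one included, gave as many genes at an unadjusted p under 0.05 (real 2491, highest other 3023). Against DOS 30 it was also 4 (real 3028, highest other 3973). With labels shuffled within slides it was 4 (highest other 2620) and 3 (highest other 3324). The DOS 300 count was the largest of 8 comparisons with corn oil, with no correction for their number, so chance was not excluded. Slide was argued against as the cause, since 2512 genes reached that p with slide as a block against 2505 without. Signal strength stays open: 4 of 6 DOS 300 arrays lay outside the range of the corn oil and DOS 30 arrays in the 75th percentile of signal. With the log2 75th percentile as a covariate 1289 genes in place of 2491 reached that p, and 1239 in place of 3028 against DOS 30. These counts are over 22029 genes, and chance gives 1109 over 22171. With limma and that covariate the smallest adjusted p was 0.737 against corn oil and 0.773 against DOS 30, and an effect of the compound cannot be told apart from signal strength here.

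Chance was also not excluded for the other results by 100 splits each, the real one included, in which arrays changed groups regardless of slide. The number of splits with as many genes at an unadjusted p under 0.05, with the real and the highest other count in parentheses, was 50 (1358, highest other 2827) for DEHP 30, 64 (742, highest other 2122) for DEHP 300, 84 (741, highest other 2539) for DINCH 30 and 94 (580, highest other 2716) for DINCH 300. It was 92 (623, highest other 2380) for BDB 30, 86 (652, highest other 3250) for BDB 300 and 55 (939, highest other 2899) for DOS 30. With both doses averaged it was 54 (1110, highest other 3190) for DEHP, 78 (679, highest other 2810) for DINCH, 80 (729, highest other 2297) for BDB and 33 (1245, highest other 3036) for DOS. It was 45 (1012, highest other 2603) for the F test, 38 (4927, highest other 7366) between doses, 67 (5748, highest other 12335) between compounds at 30 mg/kg/day and 21 (8101, highest other 11125) at 300 mg/kg/day. For genes passing on the average of the 8 exposures it was 12 (1, highest other 447). A split that calls so many genes points to a structure of the samples, and with labels shuffled within slides the highest other count was 3. For list calls it was 28 (28, highest other 77) against corn oil and 59 (41, highest other 87) between doses or compounds.

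Since those splits moved arrays across slides, the group labels were also shuffled within slides, 100 times for each result and the real labels included, and chance was again not excluded. As many genes as in the real grouping came in 13 (2579) shuffles for DEHP 30 (highest other in parentheses), 54 (1983) for DEHP 300, 43 (1841) for DINCH 30, 86 (2553) for DINCH 300, 68 (3107) for BDB 30, 75 (2257) for BDB 300 and 41 (2391) for DOS 30. Over both doses it was 22 (2114) for DEHP, 65 (2209) for DINCH, 56 (2481) for BDB and 18 (2690) for DOS, and for genes passing on the average of the 8 exposures 11 (3). The number was 8 (1370) for the F test, 7 (7345) between doses, 20 (7855) between compounds at 30 mg/kg/day and 6 (10223) at 300 mg/kg/day. List calls were as many in 34 (73) against corn oil and 73 (109) between doses or compounds.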
